A study of Mus musculus with 2 samples.

How the data were processed

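MicroRNA sequencing was carried out on 2 libraries of left cerebral cortex tissue labelled as male B6CASTF1/J mouse, 14 days of age. B6CASTF1/J is the first-generation cross of a C57BL/6 and a CAST/Ei parent strain. Per the labels, the libraries are biological replicates 1 and 2 of a single group, made from total RNA with an RNA size class of short RNAs. Both carry the same donor label and separate tissue sample records. Nothing in the labels says that they came from separate animals, so SDs measure the spread between these samples, which may be technical. The exact test of each gene compares the libraries with read sampling only and makes no allowance for such spread. There was 1 group, so no comparison between conditions exists, and the profile itself and the agreement of the 2 libraries are described.

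The deposited files hold raw read counts per microRNA gene, with no normalization by the authors. Each file gives 3 counts per gene (strand ignored, the strand of the gene, and the opposite strand), after 4 leading rows for reads that were unmapped, mapped to several positions, fell in no gene or were ambiguous. The layout is that of a STAR gene count table; the aligner, the counter and their settings are not given in the sources used here. The descriptions deposited beside the files name the mm10 assembly and GENCODE annotation M21. All 2202 gene IDs, version included, matched the microRNA genes of GENCODE M21, from which symbols, positions, host genes and hairpin sequences were taken. A gene here is a hairpin: the mature forms from its arms are not separated. A read that matched several genomic positions was not given to any gene, so genes whose mature sequence has several genomic copies are uncertain and can be counted too low. Genes that share an 18-base stretch of hairpin sequence with another, non-overlapping microRNA gene were marked for this reason; there were 1135 of them.

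The counts on the strand of the gene were used. CPM values are counts scaled to the same library total, where the total was the sum over genes, 4111167 in replicate 1 and 3189903 in replicate 2. Reads in no gene row were left out of these totals. They made up 39.1% (several positions), 19.1% (unmapped) and 5.13% (no gene) of the 11224232 reads of replicate 1, and 41.4%, 17.5% and 4.66% of the 8758378 reads of replicate 2. A gene was called detected with at least 10 counts in each library. The limit that a count of 0 allows, 3 counts, was 0.730 CPM in replicate 1 and 0.940 CPM in replicate 2. It does not hold for genes whose reads match several positions, since those reads were not counted. Shares of single libraries have exact Clopper-Pearson 95% intervals. Intervals and limits cover counting error only and treat reads as independent. Reads without molecular identifiers are not independent molecules, so intervals can be too narrow and limits too low.

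The share of counts in the 10 most abundant genes and in 21 microRNA lists was computed per library and is given as mean ± SD of 2. A list took every gene whose symbol equalled a listed symbol or that symbol with a copy number. The median log2(CPM + 1) of each list was placed among those of 10000 random lists of the same size drawn from all genes, as a description. Lists overlap: members of the list of mature sequences with several genomic copies are also in other lists. Pearson and Spearman correlations used log2(CPM + 1) over detected genes. The biological coefficient of variation is the square root of the common dispersion from edgeR (intercept only, TMM factors). Each detected gene's split of counts between the libraries was set against the split of the library totals with a two-sided exact binomial test and Benjamini-Hochberg adjustment over detected genes, threshold 0.05. Such a test compares 2 libraries and no conditions. With 2 libraries of 1 group no exact test over samples can pass 0.05: the smallest two-sided p of an exact sign-flip test is 0.5. No test over samples is reported.

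Genes named in the text follow a rule: the 25 with the highest mean CPM among detected genes, the 3 most abundant members of each list, up to 4 members of each list with 0 counts in both libraries, and the 10 with the largest ratio between the libraries among those past the exact test with a mean of at least 50 counts. The lists, the naming rule, the tests of the results in the report and the alternatives were fixed before the data were examined; most tests of explanations in the closing section were chosen later, as stated there. The alternatives were the counts that ignore strand, no count minimum or a minimum of 50, pseudocounts of 0.1 and 10, size factors from DESeq2 or TMM, an adjusted p under 0.01, leaving out the most abundant gene or member, and leaving out each replicate. The choice of the let-7, Dlk1-Dio3 and neuron-associated lists as the leading lists was made after their shares were seen.

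The procedures were tested on simulated counts drawn from these libraries' means and totals. Of 200 genes given a change, 185 reached the count minimum and were tested with 222 unchanged genes, 407 in all. The exact test called 65.7% of 67 genes with a 1.5-fold change, 80.3% of 66 with a 2-fold change and 89.6% of 67 with a 4-fold change. The 15 changed genes under the minimum count as not called. It called 2 of the 222 unchanged genes. For this test the counts were drawn with Poisson noise alone, so those 2 calls give no error rate for libraries that differ beyond read sampling. The simulated counts were also tested against the split they were drawn with, so errors from scaling to library totals were not covered. A simulated coefficient of variation of 0.3 was estimated as 0.290 over 415 genes. Work was done in Python 3.11.15 (numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9) and R 4.3.3 (edgeR 4.0.16, DESeq2 1.42.0).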

Results

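MicroRNA abundance was measured by small RNA sequencing in left cerebral cortex tissue labelled as male B6CASTF1/J mouse, 14 days of age. There were 2 replicate libraries of 1 group, and the labels do not say whether they came from separate animals. Replicate 1 held 11224232 reads and replicate 2 held 8758378. On average 36.5% ± 0.146 (SD, n = 2) of the reads were counted in a microRNA gene on its own strand, which left 4111167 and 3189903 counts. Reads that matched several genomic positions, which were given to no gene, made up 40.2% ± 1.62 (SD, n = 2), or 1.10 ± 0.0486 times the counted reads. Of 2202 microRNA genes, 466 had at least 10 counts in replicate 1, 419 in replicate 2 and 406 in both.

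**Figure D1:**
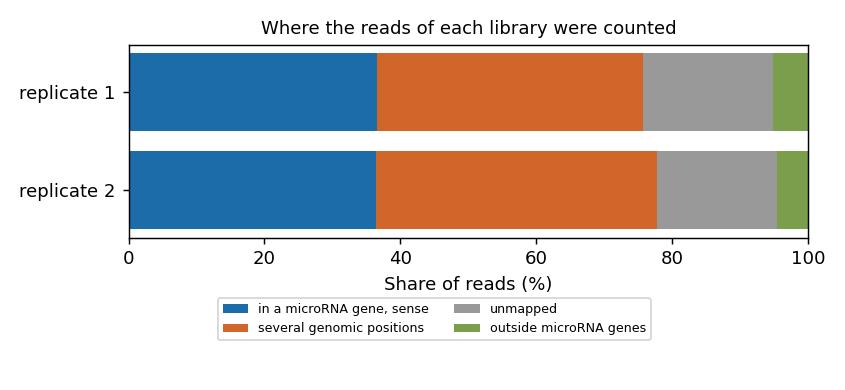
Share of the reads of each library (horizontal axis, percent) that was counted in a microRNA gene, matched several genomic positions, was unmapped or lay outside microRNA genes. Each bar is 1 library; the part with several positions, 39.1% in replicate 1 and 41.4% in replicate 2, is larger than the counted part, 36.6% and 36.4%.

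Among the counted reads, Mir139, members of the let-7 family and microRNAs of the Dlk1-Dio3 imprinted region led the cortical profile. Reads that matched several positions are not in this ranking, so microRNAs with several genomic copies can rank too low. Mir139 (ENSMUSG00000065446.1; mm10 chromosome 7, 101475376 to 101475443, plus strand, in an intron of Pde2a, which encodes a cyclic nucleotide phosphodiesterase) was the most abundant gene at 92324 ± 13062 CPM (SD, n = 2), or 9.23% ± 1.31 of the counts. The 10 most abundant genes held 48.0% ± 1.77 of the counts, and the leading 25 held 69.9% ± 0.0294. The leading 100 held 94.6% ± 0.203. Genes of the leading 25 that belong to none of the lists included Mir744 in an intron of Map2k4 (27052 ± 5025 CPM), Mir149 in an intron of Gpc1 (21503 ± 8754 CPM), Mir99a in an intron of Mir99ahg (17107 ± 5008 CPM), Mir298 on chromosome 2 (16333 ± 11065 CPM), Mir23b (14812 ± 683 CPM), Mir22 (13253 ± 6171 CPM), Mir652 (12128 ± 1352 CPM), Mir125a (11729 ± 1174 CPM) and Mir191 (9335 ± 523 CPM). Mir298 differed most between the libraries within this set, at 8509 CPM in replicate 1 and 24157 CPM in replicate 2.

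The let-7 family, whose mature forms accumulate as cells differentiate, held the largest share of the counts among the 21 lists, 26.1% ± 0.598 (SD, n = 2). All 12 members were detected. Mirlet7g, in an intron of Wdr82 (chromosome 9, 106178840 to 106178927), stood at 74187 ± 4031 CPM. Mirlet7i (chromosome 10, 122985640 to 122985724, in an exon of the non-coding gene D630033A02Rik) stood at 70793 ± 2428 CPM, and Mirlet7b (chromosome 15, 85707319 to 85707403, in an exon of the non-coding gene Lncppara) at 53748 ± 106 CPM. Mirlet7d (29213 ± 1167 CPM) and Mirlet7e (22968 ± 344 CPM) were also among the leading 10 genes. Of the 12 members, 9 share an 18-base stretch with another microRNA gene, so their counts are uncertain. Between the libraries 6 members were higher and 3 lower in replicate 2 past the exact test, and 3 did not pass it; with TMM library sizes 9 were higher and 2 lower.

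The Dlk1-Dio3 list, named for an imprinted region whose microRNAs are expressed from the maternal chromosome, held 21.9% ± 0.636 of the counts (SD, n = 2). Of its 58 members, 50 were detected and 25 reached at least 1000 CPM. On chromosome 12 lie 57 of the members, between 109563692 and 109747960; Mir496b lies on chromosome 19. Mir127 (39262 ± 1857 CPM), Mir770 in an exon of Meg3 (39018 ± 5557 CPM), Mir487b (31244 ± 2225 CPM), Mir433 (19914 ± 822 CPM), Mir382 in an exon of Mirg (19697 ± 1027 CPM) and Mir541 in an intron of Mirg (11021 ± 377 CPM) were among the leading 25 genes. Mir432, Mir453, Mir299b and Mir496b, which share no 18-base stretch with another microRNA gene, had 0 counts in both libraries, which allows up to 0.730 CPM in replicate 1 and 0.940 CPM in replicate 2. The let-7 share was 1.19 ± 0.0619 times that of this list. An 18-base stretch is shared with another microRNA gene by 9 of the 12 let-7 members and 7 of these 58. Reads left out can therefore weigh unequally on the 2 shares, and the ratio is uncertain. Past the exact test 14 members were higher and 27 lower in replicate 2, and 9 did not pass; with TMM library sizes 15 were higher and 20 lower, and 15 did not pass.

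**Figure D2:**
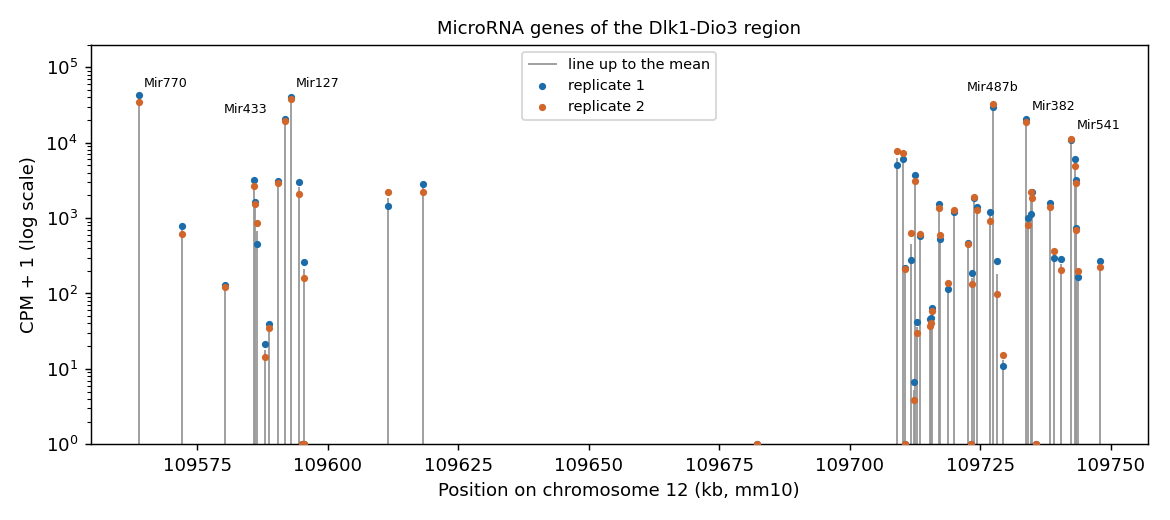
Abundance (CPM + 1, log scale) of the 57 microRNA genes of the Dlk1-Dio3 list on chromosome 12 against their position (kb, mm10). Points are the 2 libraries and grey lines rise to the mean of each gene; Mir770, Mir127 and Mir487b are the highest, and genes on the bottom line had 0 counts.

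Neuron-associated microRNAs held 15.4% ± 0.966 of the counts (SD, n = 2), of which Mir139 alone made up 59.8%. With Mir139 left out of the list and of the total, the list held 6.80% ± 0.277 of the remaining counts. Of 27 members 20 were detected. After Mir139 the leading members were Mir132, which is induced by neuronal activity (chromosome 11, 75173682 to 75173747; 16177 ± 5583 CPM), Mir128-1 in an intron of R3hdm1 (14152 ± 150 CPM) and Mir137 (9846 ± 908 CPM). Mir344 and Mir344-2 had 0 counts in both libraries. Both share an 18-base stretch with another microRNA gene, so their 0 counts set no limit on abundance. Of the 27 members, 19 share an 18-base stretch with another microRNA gene. Their counts can be too low, so the list share, its rank among the lists and the part held by Mir139 are uncertain. Some members with several genomic copies and few counts are named in the closing section. Past the exact test 7 members were higher and 12 lower in replicate 2, and 1 did not pass; with TMM library sizes 8 were higher and 10 lower.

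Lists named for some other cell types of brain tissue held smaller shares, and none of the lists was named for astrocytes. The endothelial list held 1.18% ± 0.193, nearly all from Mir126a in an exon of Egfl7 (11812 ± 1929 CPM), while Mir126b on the opposite strand had 1 count per library. With strand ignored the endothelial share was 3.92e-05%, since Mir126a then lost its counts to the overlap. The microglia and leukocyte list held 0.889% ± 0.163, led by Mir342 in an intron of Evl (6903 ± 1531 CPM), with Mir146 (986 ± 148 CPM) and Mir150 (813 ± 20.0 CPM) below it. The smooth muscle and pericyte list held 0.515% ± 0.0101, with Mir143 at 4928 ± 124 CPM and Mir145a at 218 ± 23.1 CPM. The oligodendrocyte-associated list held 0.270% ± 0.0236, from Mir219a-2 (1531 ± 128 CPM) and Mir338 in an intron of Aatk (1157 ± 107 CPM). Both have a microRNA gene on the opposite strand, and with strand ignored the share was 1.68e-05%. Of its 5 members 4 share an 18-base stretch with another microRNA gene, Mir219a-2 among them. The share, and any ratio to it, is uncertain for that reason. The choroid plexus and ciliated cell list held 0.113% ± 0.0262, led by Mir204 in an intron of Trpm3 (655 ± 103 CPM). The neuron-associated share was 57.2 ± 1.41 times the oligodendrocyte-associated share, 17.7 ± 4.34 times the microglia and leukocyte share and 13.3 ± 2.99 times the endothelial share; these are ratios of counts, and Mir139 sets most of the numerator. Most neuron-associated members share an 18-base stretch with another microRNA gene, so the numerator can be too low. The denominators rest on few genes too: with its leading member left out, the microglia and leukocyte list held 0.200% and the endothelial list 2.82e-05% of the remaining counts.

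Lists named for cells outside the cortex held far smaller shares. The epithelial list held 0.0203% ± 0.00271, led by Mir203 (114 ± 13.4 CPM). The erythroid list held 0.00941% ± 0.00257, with Mir451a at 53.8 ± 23.7 CPM, and 0.00162% with strand ignored. The pancreas list held 0.00927% ± 0.00400, with Mir375 at 66.2 ± 32.7 CPM. Liver-specific Mir122 stood at 49.9 ± 2.72 CPM. The Hox cluster list, for hindbrain and spinal cord, held 0.00442% ± 0.00199, led by Mir10b at 37.5 ± 17.0 CPM. The skeletal and cardiac muscle list held 0.00328% ± 0.000113, with 2 of 11 members detected; Mir206 stood at 22.3 ± 2.23 CPM, and Mir133a-1, Mir133a-2, Mir1a-1 and Mir1a-2 had 0 counts in both libraries. Of the 11 members 6 share an 18-base stretch with another microRNA gene, these 4 among them, so their 0 counts set no limit on abundance. The sensory list, for photoreceptors and hair cells, held 0.00165% ± 0.000383, led by Mir182 at 8.50 ± 4.49 CPM. None of the 14 members of the pluripotent cell list was detected in both libraries; their summed share was 0.000754% in replicate 1 (exact 95% interval 0.000512 to 0.00107%) and 0.000219% in replicate 2 (8.82e-05 to 0.000452%).

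**Figure D3:**
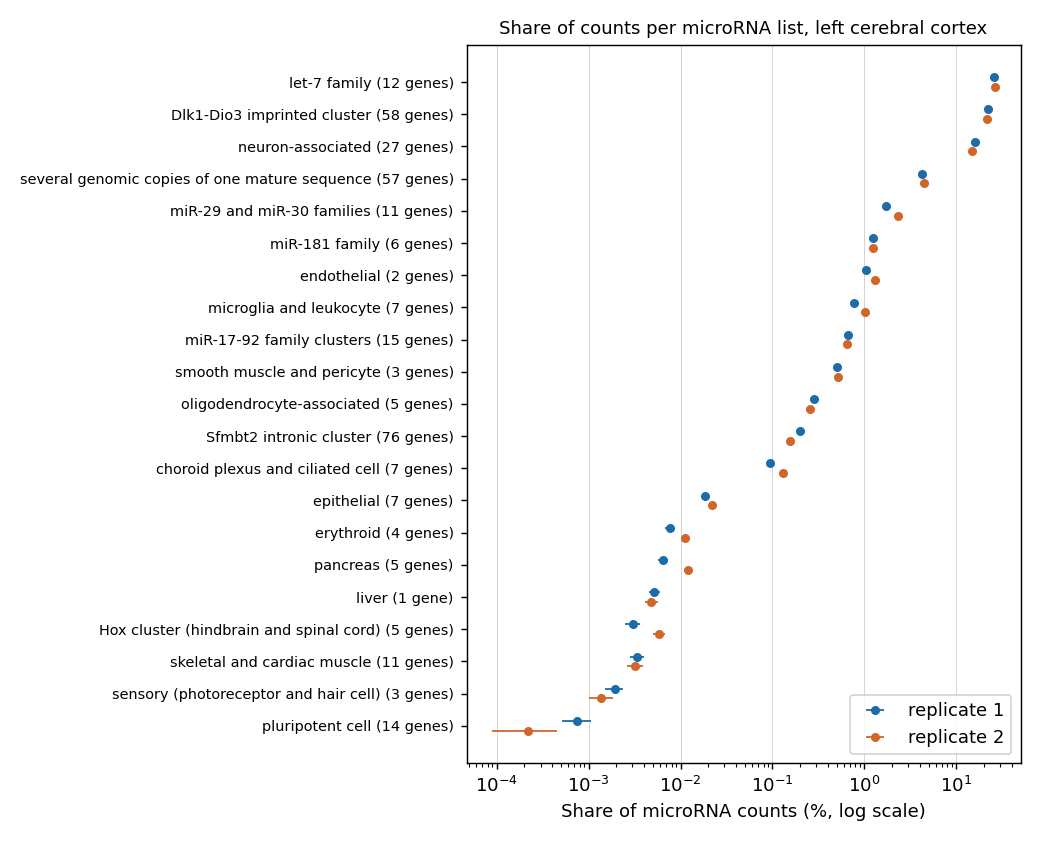
Share of the microRNA counts (horizontal axis, percent, log scale) held by each of the 21 lists, with the number of genes in each. Points are the 2 libraries and bars their exact 95% binomial intervals, which cover counting error of independent reads only. The let-7 family, Dlk1-Dio3 and neuron-associated lists lie at 26.1, 21.9 and 15.4% on average, and the pluripotent cell list lies lowest.

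Set against 10000 random lists of the same size, the median abundance of the let-7 and Dlk1-Dio3 lists lay above that of 100% of them, that of the oligodendrocyte-associated list above 97.2%, that of the pluripotent cell list above 84.2% and that of the muscle list above 0%, where 84.4% of random lists had the same median of 0; most genes had few or no counts, so a low median still ranks high. Among the remaining families, the miR-29 and miR-30 families held 2.02% ± 0.413 of the counts, led by Mir30d (9303 ± 5176 CPM). The miR-181 family held 1.25% ± 0.00635, with all 6 members detected and Mir181b-2 at 4276 ± 107 CPM. The miR-17-92 family clusters, associated with proliferation, held 0.654% ± 0.0161, led by Mir93 (2302 ± 115 CPM), which overlaps an exon of Mcm7, and Mir17 (2018 ± 36.8 CPM). In the Sfmbt2 intronic cluster, 8 of 76 members were detected and the list held 0.178% ± 0.0327; Mir467d led it at 784 ± 146 CPM. Of these 76 genes 75 share an 18-base stretch with another microRNA gene. So do 9 of the 11 members of the miR-29 and miR-30 list, 4 of the 6 of the miR-181 list and 4 of the 15 of the miR-17-92 list. Counts of these families are uncertain for that reason. The list of mature sequences with several genomic copies held 4.39% ± 0.166, with 40 of 57 members detected, led by Mir128-1, Mir128-2 (5185 ± 739 CPM) and Mir138-1 (4807 ± 235 CPM).

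The replicate libraries ranked the microRNAs alike, while many single genes differed by more than sampling of independent reads gives; reads without molecular identifiers are not independent molecules. Mir26a-2 had 52 counts in replicate 1 and 1175 in replicate 2, a log2 ratio of CPM of 4.86, the largest among the genes named for their ratio. Also higher in replicate 2 were Mir200b (log2 ratio 3.11; adjusted p = 2.57e-32, exact binomial test), Mir674 (2.06), Mir21a (1.75) and Mir181a-2 (1.71). Lower in replicate 2 were Mir185 (-2.97), Mir153 (-2.69), Mir3547 (-2.39; adjusted p = 4.49e-88, exact binomial test), Mir505 (-2.18) and Mir187 (-1.98). Mir26a-2 and Mir181a-2 share sequence with another microRNA gene and are uncertain for that reason. Mir153 shares no such stretch but is on the list of mature sequences with several genomic copies, so it is uncertain too.

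Across the 406 detected genes Pearson's correlation of log2(CPM + 1) was 0.984 and Spearman's 0.981; these are correlations across genes, which are not independent replicates. The median absolute log2 ratio was 0.30, against 0.05 from sampling of reads alone, and 366 genes (90.1%) lay within 2-fold. The biological coefficient of variation was 0.307. A chi-square of 160190 on 405 degrees of freedom is above what 2 runs of 1 library gave when reads were sampled independently (345 to 491 in 100 simulated pairs), so they were kept as 2 libraries. By the exact binomial test with Benjamini-Hochberg adjustment 236 genes differed between the libraries, 95 higher and 141 lower in replicate 2. With TMM library sizes, which move every log2 ratio by 0.08, the split was 111 higher and 110 lower, and with DESeq2 size factors 112 and 108. Over 2-fold apart were 39 genes, 21 higher and 18 lower in replicate 2; with TMM library sizes there were 44, 28 higher and 16 lower.

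**Figure D4:**
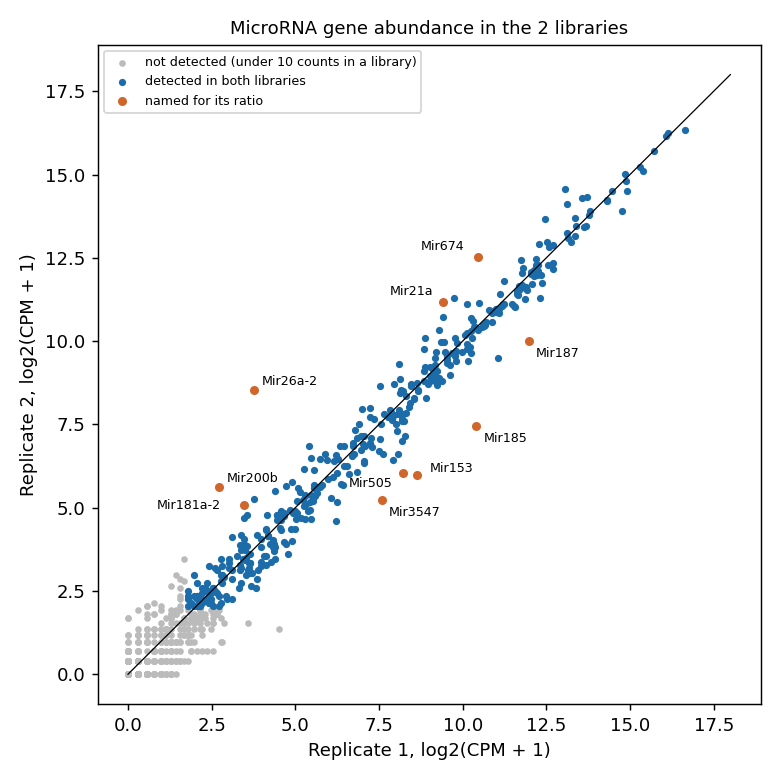
Abundance of each microRNA gene, log2(CPM + 1), in replicate 1 (horizontal) and replicate 2 (vertical), with the line of equal values. Blue points are the 406 genes detected in both libraries, grey points the others, and the 10 labelled orange points are the genes named for their ratio, of which Mir26a-2 lies farthest from the line.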

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

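Both tests of an explanation in this part were chosen after the counts had been seen.

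Signal lay outside the counts used for the profile. Reads that matched several genomic positions made up 39.1% of the reads of replicate 1 and 41.4% of replicate 2, more than were counted in genes. Counts on the strand opposite to a microRNA gene with no microRNA gene annotated there came to 154 in replicate 1 and 107 in replicate 2. They are given because they lie outside the counts used, and they are few: 37.5 and 33.5 CPM when scaled to the same library totals as the profile, with 39 in each library from Mir3083, a gene chosen after its values were seen.

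Several neuron-associated microRNAs with several genomic copies had few counts: Mir124a-1, Mir124a-2 and Mir124a-3, known as abundant in neurons and chosen here after their values were seen, had 9, 11 and 2 counts in replicate 1 and 19, 3 and 8 in replicate 2. Others with several copies had many: Mir128-1 had 57746 counts in replicate 1 and 45484 in replicate 2, and Mir138-1 had 19078 and 15864. Counts at these genes come only from reads that matched a single position, and the hairpin arms are not separated. The reads left out came to 39.1% of the reads or more in each library, but how many of them are microRNA reads was not analysed here, so whether they could hold the missing counts stays open. Loss of reads to several positions is a candidate explanation. The median log2(CPM + 1) of the 19 members that share an 18-base stretch with another microRNA gene was 6.40, against 11.65 for the other 8, a difference of -5.25. The same list showed the pattern, so this difference is no independent support. The permutation test missed 0.05 (two-sided p = 0.0544), and the bound that would have counted against this explanation was set after that p was known, so it stays open. A low level in this tissue is neither shown nor excluded by these counts, since reads that matched several positions were given to no gene. The mature sequences of the left-out reads were not analysed here.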

How the results depend on the processing

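Of 48 values of the main results under alternatives, 10 are shares with a replicate left out, which with 2 libraries cannot move by more than their SD and so say nothing about stability. Of the other 38, 27 stayed within the tolerance and 11 did not; the tolerance was 1 SD for shares, 1.5 times for counts and for the coefficient of variation, and the 95% range from resampling genes for the correlation. With no count minimum 781 genes had a count, since single counts then suffice. Ignoring strand raised the share of the 10 most abundant genes to 51.4% and that of the neuron-associated list to 16.4%. Leaving out Mir139 gave 45.1% for the 10 most abundant genes, 28.7% for let-7, 24.1% for Dlk1-Dio3 and 6.80% for the neuron-associated list; leaving out each list's own leading member gave 20.2% for let-7, 18.7% for Dlk1-Dio3 and again 6.80%. These are shares of the counts of the genes left, and the moves follow from the genes removed. The correlation at a minimum of 50 counts was 0.974, and the cause was not tested. Without either replicate, values ranged from 46.7 to 49.2% for the 10 most abundant genes and from 419 to 466 genes detected. For the other 18 lists, leaving aside 36 values with a replicate left out, 23 values stayed and 31 moved: ignoring strand raised 4 and lowered 3, from 1.18 to 3.92e-05% for the endothelial, from 0.270 to 1.68e-05% for the oligodendrocyte-associated and from 0.00941 to 0.00162% for the erythroid list. Leaving out Mir139 raised 7, none by over 1.5 times, and leaving out the leading member lowered 17, of which 16 by over 1.5 times. Ignoring strand lost 6.88 and 6.84% of the counts, because 64 genes have a microRNA gene annotated on the opposite strand. Depth limits genes near 1 CPM. No paired analysis was possible because there is 1 group, so no replicate numbers are shared between groups.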

Other observations

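Of the tests of explanations in this part, those of hairpin GC content by rank correlation were written before their results were seen; those of counting noise, of whole clusters, of the straight-line fit and of shared sequence within clusters were chosen afterwards, as were the genes named here.

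Genes within an intron of a host gene on the same strand held 44.6% ± 1.56 of the counts (SD, n = 2; 188 of 814 genes detected), genes that overlap an exon of a host gene 34.0% ± 0.748 (105 of 365) and genes with no host on their strand 21.4% ± 0.811 (113 of 1023). Chromosome 12 held 22.7% ± 0.512 of the counts, chromosome 7, home of Mir139, 10.8% ± 1.39, and chromosome 9 10.1% ± 0.703. Snord43, annotated as a microRNA gene under a small nucleolar RNA symbol, stood at 78.1 ± 52.3 CPM. Mir9-3, Mir9-1 and Mir9-2, another neuron-associated family with several copies, had 355, 44 and 1 counts in replicate 1 and 367, 84 and 9 in replicate 2.

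The detected genes differed between the replicates by a median absolute log2 ratio of 0.30. The highest of 1000 resamplings of the reads gave 0.07, but reads are not independent molecules and the libraries were single samples, so this sets no bound on counting noise, which stays open. Base composition stays open as well: the rank correlation of log2 ratio with hairpin GC percent across the 406 genes was -0.143 (permutation p = 0.00389), between the bounds set beforehand, and the median was 0.29 after a straight-line trend was removed. Whether whole clusters differed in transcription is open too: neighbours within 10 kb differed by 0.828 times the shuffled value (108 pairs, permutation p = 0.0536), which meets neither bound. Library preparation and a difference between the tissue samples were not tested.

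Neighbouring microRNA genes had unlike counts: in the cluster on chromosome 14, Mir17 had 8402 and 6353 counts and Mir20a 2251 and 1615, while Mir19a had 1 and 0 and Mir19b-1 had 4 and 0. A rise of abundance with hairpin GC percent is argued against, since within 48 clusters of 171 genes the rank correlation was -0.0761 (permutation p = 0.406, permutation SD 0.0911). Sequence shared with other loci may account for part: in 31 clusters of 270 genes the mean log2(CPM + 1), centred within clusters, was lower in the sharing genes by a difference of -0.72 (permutation p = 0.0022). Mir19a shares no such stretch, so its count is left open by that test. No biological explanation was tested, since the design gives 1 group.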
